A study of Mus musculus with 40 samples.

How the data were processed

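The samples are 20 mouse hearts, of which 6 had a sham operation and 14 had 2 weeks of transverse aortic constriction (TAC). The labels give coronal heart sections without the right ventricle. Total RNA was taken from each for a library of polyadenylated RNA (mRNA), and cleared lysate was taken for immunoprecipitation of Ago2 and a library of the bound RNA (RISC). The 40 libraries are single-end and not strand-specific, from Illumina HiSeq instruments, so overlapping or antisense genes cannot be told apart. The labels give all mice as male and 12 weeks old, while the series text gives an age range. Age was not used here. The labels call the control operation sham, while the tables for all libraries mark these hearts as without surgery.

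Per the submitters' processing notes the reads were aligned to mm10 with Bowtie2 and TopHat (TopHat2 2.0.10) and counted with HTSeq, and DESeq and edgeR are also named. The deposited values are raw counts of reads per gene, in a file per library, for 23420 gene symbols. The authors also give tables of the same counts for all libraries of a kind; their 20 mRNA and 20 RISC columns were identical to the files per library, apart from 27 symbols that a spreadsheet had turned into dates. The files per library were used. Each holds 5 rows for reads that belong to no gene (no feature, ambiguous, low quality, not aligned, not unique), which were left out of the analysis. Reads in these rows, nearly all of them not unique or ambiguous, were a mean of 11.5% in mRNA and 4.09% in RISC libraries. Reads with more than 1 alignment were not counted, so levels within families of paralogs and pseudogenes (ribosomal proteins, histones, hemoglobins, the 2 insulin genes) are uncertain. Positions on mm10, counted from 1, and transcript lengths (the union of a gene's exons) come from the gene models that the authors deposited. Positions are printed with the strand of the gene.

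Samples were grouped by genotype (non-transgenic, ntg, or transgenic for miR-378a, TG), operation and kind of library, as in the labels: 3 ntg sham, 3 TG sham, 7 ntg TAC and 7 TG TAC hearts. A replicate number joins the mRNA and the RISC library of a heart, since their names carry the same animal code. This was tested on the data: over 7799 genes with a mean of at least 5 CPM, residuals from the group means of the libraries of a heart correlated above 0.1 in 16 of 20 hearts, and 16 of 20 RISC libraries correlated best with the mRNA library of their own number (median 0.176, range -0.044 to 0.333). Across genotypes the same number did not pair hearts in mRNA (median correlation -0.033 in sham and -0.024 in TAC). In RISC the medians were 0.083 in sham and 0.118 in TAC, where 7 of 7 numbers were positive (0.05 to 0.195; 0.004 for different numbers), but 2 of 7 libraries correlated best with their own number. Numbers were not taken to pair hearts across genotypes, and the replicate number as a block was an alternative.

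Depth was 15.1 ± 3.4 M gene counts in mRNA (mean ± SD) and 17.6 M in RISC libraries. A mean of 16511 genes was detected per mRNA library and 15297 per RISC library. The biological coefficient of variation of the edgeR models was 12.9% in mRNA, 16.6% in RISC and 14.6% where both were modelled together.

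Analyses used R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Counts were filtered with filterByExpr and normalized with TMM, and genes were tested with edgeR's quasi-likelihood test with robust estimation of the dispersions. p values were adjusted with the Benjamini-Hochberg method over all tested genes of a comparison, and a gene was called at an adjusted p below 0.05. Each fit held all groups of a kind of library. The standard error of a log2 fold change is its size divided by the square root of the F statistic. There were 13 comparisons: TG against ntg in sham and in TAC hearts, TAC against sham in ntg and in TG hearts, and the difference of the transgene effect between TAC and sham, for mRNA and for RISC, and the 3 of these that involve the transgene effect for RISC relative to mRNA. RISC relative to mRNA is the log2 fold change in RISC less that in mRNA, from 1 model of all libraries. Fold changes are log2 values, and CPM are gene counts scaled to a common library total.

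Gene lists, 24 in all, were fixed before the data were examined and compared with limma's camera at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison, and again with the correlation estimated from the data. Adjustment over a list alone takes only the p values of its members. Lists were measured by the members that passed the filter, so their sizes differ between kinds of library. Genes were named by a rule fixed beforehand: the gene of the miR-378 precursor, its host gene and the gene of Ago2; the 6 higher and 6 lower called genes with the largest fold changes and a mean of at least 1 CPM; up to 4 called members of each list with a call (2 for lists over 30 genes); markers of overload in TAC comparisons; and reported targets of miR-378 in TG comparisons. Not all are printed, and 2 members of the list of miR-378 targets are not reported here by themselves, though the list's values include them. Other genes are said to be chosen after their values were seen.

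The overlap of calls between sham and TAC hearts was compared with the number that independent lists of these sizes would share. The sex-linked check used Xist and 4 Y-linked genes with a limit of 20 CPM. The adipocyte score of a library is the mean log2 CPM of the adipocyte list with a pseudocount of 0.5. The length slope of a library is the slope of its log2 levels, relative to the mean of all libraries, on log2 transcript length. Lists were compared with 10000 random lists matched on length and level, drawn from the 20 nearest genes of each member. Similarity of libraries was measured as chi-square per gene between pairs, for genes with at least 20 counts in a pair, where 1 is counting noise alone. Groups of 7 were tested with Dixon's test for a value far from the others, and shares of reads without a unique alignment with exact two-sided permutation tests.

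The pipeline was tested on simulated data: counts were drawn with the depths and dispersions of the libraries and no differences between groups except for 200 genes changed in 1 group. At a 2-fold change the test found 68% of them in the sham comparison of mRNA and 90% in the TAC comparison, 44.8% and 76.8% in RISC, and 15% and 71% for RISC relative to mRNA. For the difference of the transgene effect it found 65% in mRNA, 22.6% in RISC and 4% for RISC relative to mRNA. At a 1.5-fold change the shares were 33% and 70.4% in mRNA and 3.16% and 36.4% in RISC. False calls were 1.41% to 28.6% of the calls. The test found 82.8% and 78% for TAC against sham in ntg and TG mRNA at 2-fold.

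Alternatives chosen beforehand were DESeq2 size factors in edgeR, no filter on low counts, the DESeq2 Wald test, a fit of only the compared groups, a block (the replicate number, or the heart for RISC relative to mRNA), each replicate left out in turn, camera with an estimated correlation or in the blocked fit, and for the overlap an adjusted p below 0.1 or DESeq2 calls. Alternatives chosen after seeing the data were the adipocyte score, presence of islet transcripts (Ins2 above 10 CPM) and the length slope as covariates, Rn45s counts left out, the shallow RISC libraries ntg TAC 5 and ntg TAC 6 left out, and the near-identical RISC libraries TG TAC 3 and TG TAC 7 summed as 1. Other splits of the samples were drawn at most 100 times per comparison. A planned test of genes with miR-378 seed sites was not run, since no genome or 3' UTR sequence came with the files.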

Results

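RNA was measured in 20 hearts of FVB/N mice that were non-transgenic (ntg) or carried a transgene overexpressing miR-378a (TG). The series studied what this microRNA does to the messages of the heart, at rest and under pressure overload. The hearts came from 3 ntg and 3 TG mice after a sham operation, and from 7 ntg and 7 TG mice after 2 weeks of transverse aortic constriction (TAC). The labels give every mouse as male and 12 weeks old. The labels call the control hearts sham, while the series tables mark the same libraries as without surgery, so whether the control hearts were operated is not settled here. Each heart gave a library of polyadenylated RNA (mRNA) and a library of RNA bound by immunoprecipitated Ago2 (RISC), so 40 libraries were compared. The mRNA libraries held 9.98 to 25.5 M gene counts (mean 15.1 M), and the RISC libraries held 7.55 to 25.4 M (mean 17.6 M). The ribosomal RNA precursor Rn45s took 48.5% to 62.3% of the RISC counts, which left 3.49 to 10.6 M counts for all other genes; in mRNA it took 5.34% to 11.3%. Mean RISC depth was 13.9 M counts in ntg TAC and 19.5 M in TG TAC hearts. The gene of the miR-378 precursor, Mir378, held 0 counts in every library, which still allows up to 3 counts per library, so the transgene's own product was not measured by these counts. Adjusted p values come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and fold changes are log2 values with their standard error (SE). Gene lists were compared with camera, again with Benjamini-Hochberg adjustment.

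Sex-linked genes differed by operation and not by genotype. In the 6 sham mRNA libraries Xist, the RNA that silences an X chromosome in female cells (chromosome X, 103460373 to 103483233, minus strand), stood at 117 to 142 CPM, and the Y-linked genes together at 0.216 to 4.88 CPM. In the 14 TAC mRNA libraries Xist stood at 1.03 to 3.48 CPM and the Y-linked genes at 79.9 to 122 CPM. RISC libraries of the same hearts showed 0.167 to 1.69 CPM of Y-linked RNA in sham and 41.2 to 61 CPM in TAC. Every comparison of TAC with sham therefore also compares hearts with Y-linked RNA to hearts with Xist, while TG and ntg hearts of the same operation were alike in both. The mean level of adipocyte genes in mRNA also differed by group: 5.22 ± 0.12 log2 units in ntg sham, 2.29 ± 0.525 in TG sham, 2.81 ± 1.1 in ntg TAC and 2.35 ± 0.818 in TG TAC hearts (mean ± SD). RISC libraries differed in short transcripts. Length slopes were 0.0711 ± 0.0372 in ntg TAC, -0.0514 ± 0.0477 in TG TAC, -0.01 in ntg sham and -0.037 in TG sham.

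**Figure D1:**
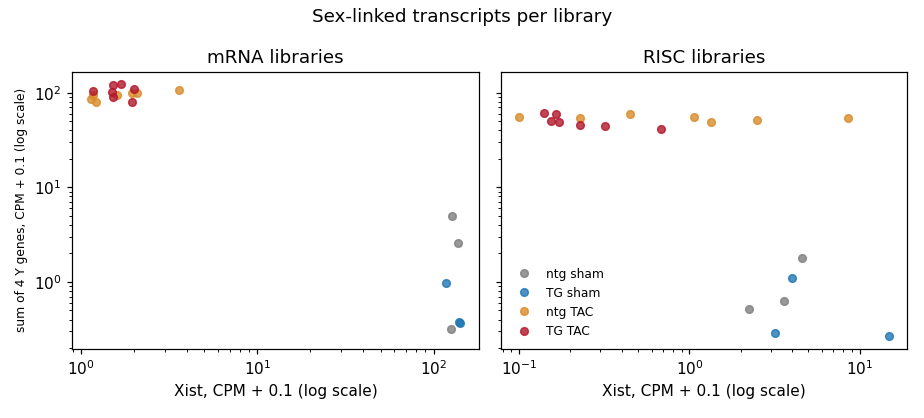
Xist and the summed Y-linked genes in each library, in CPM. Sham mRNA libraries lie at 117 to 142 CPM of Xist, and TAC mRNA libraries at 1.03 to 3.48 CPM.

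At rest, miR-378a overexpression left the heart with less mRNA for 2 abundant muscle proteins and more mRNA for a skeletal-muscle calcium channel. Single genes of contraction, potassium currents and fatty acid use were lower as well, among them Kcnip2, Casq2 and Acsl1. Adipocyte genes lay highest in the 3 ntg sham hearts. In mRNA of sham hearts 1297 genes were higher and 1330 lower in TG than in ntg, of 14141 tested.

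Cmya5, which encodes the muscle protein myospryn (chromosome 13, 93040715 to 93144724, minus strand), stood at 975 ± 6.34 CPM in ntg sham and 188 ± 29.1 CPM in TG sham hearts (mean ± SD, n = 3 each). Its log2 fold change was -2.38 (SE 0.13, adjusted p = 1.12e-11). Hspb6, a small heat shock protein of cardiac muscle (chromosome 7, 30553302 to 30555439, plus strand), fell from 1630 ± 34.7 to 235 ± 79.9 CPM, a log2 fold change of -2.79 (SE 0.22, adjusted p = 3.57e-08). In this comparison Cmya5 and Hspb6 were chosen after their values were seen. Ryr1, the ryanodine receptor of skeletal muscle (chromosome 7, 29003340 to 29125151, minus strand), rose from 0.323 ± 0.13 to 6.56 ± 1.55 CPM (log2 fold change 4.31, SE 0.47, adjusted p = 1.01e-06). Ano5, a membrane protein mutated in a limb-girdle dystrophy, rose by 3.18 (SE 0.29, adjusted p = 7.93e-08), and the ubiquitin ligase gene Rnf208 rose by 3.39 (SE 0.3, adjusted p = 4.14e-08). The matricellular gene Wisp1 fell by 3.72 (SE 0.43, adjusted p = 1.56e-06). Kcnip2, which encodes a subunit of the transient outward potassium channel (chromosome 19, 45792346 to 45816063, minus strand), went from 246 ± 18.1 to 97 ± 20 CPM (log2 fold change -1.35, SE 0.13, adjusted p = 7.93e-08). Casq2, the calcium store protein of the sarcoplasmic reticulum, fell by 0.73 (SE 0.09, adjusted p = 7.71e-06). Acsl1, which activates fatty acids (chromosome 8, 46471042 to 46536050, plus strand), fell by 0.84 (SE 0.1, adjusted p = 1.9e-06). Cd36, a fatty acid transporter, fell by 0.76 (SE 0.12, adjusted p = 0.000121). Herpud1, an endoplasmic reticulum stress gene, fell by 1.09 (SE 0.15, adjusted p = 1.63e-05), and the ribosomal protein gene Rps6 fell by 0.96 (SE 0.16, adjusted p = 0.000157). Hist2h2be, a core histone whose message is partly polyadenylated, rose by 1.28 (SE 0.2, adjusted p = 8.49e-05). Adjusted p values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

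Of 22 measured genes of adult contraction, calcium handling and potassium currents, 12 fell and 1 rose, with the same 12 and 1 when adjusted over the list alone. Camera placed this list lower with adjusted p = 1.94e-05, and with adjusted p = 0.136 with an estimated correlation. Of 27 fatty acid oxidation genes 11 fell and 1 rose (12 and 2 adjusted over the list alone), with camera adjusted p = 9.55e-05 and adjusted p = 0.662 with an estimated correlation. All of the 10 adipocyte genes were lower when adjusted over the list alone, and 6 were called among all genes (camera adjusted p = 2.02e-05; adjusted p = 0.334 with an estimated correlation). Ucp1, the uncoupling protein of brown fat (chromosome 8, 83290348 to 83298456, plus strand), stood at 57 ± 18.1 CPM in ntg sham and 0.353 ± 0.159 CPM in TG sham hearts (log2 fold change -7.25, SE 1.21, adjusted p = 0.000561, edgeR). Of 77 ribosomal protein genes 13 fell, also adjusted over the list alone (camera adjusted p = 9.55e-05; adjusted p = 0.898 with an estimated correlation). Of 10 fibroblast genes 4 fell (5 adjusted over the list alone; camera adjusted p = 0.00506; adjusted p = 0.334 with an estimated correlation). Of 16 histone genes 7 rose, and 7 adjusted over the list alone (camera adjusted p = 0.00244; adjusted p = 0.263 with an estimated correlation). With the adipocyte level, which separates the genotypes here, as a covariate chosen after seeing the data, 827 genes were called in place of 2627. Folds changed little (median ratio 0.972) and standard errors grew (1.44). Ucp1 is in that level, so is not tested (-0.78, SE 2.48). Cmya5, Hspb6, Ryr1, Kcnip2, Casq2 and Acsl1 stayed called.

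**Figure D2:**
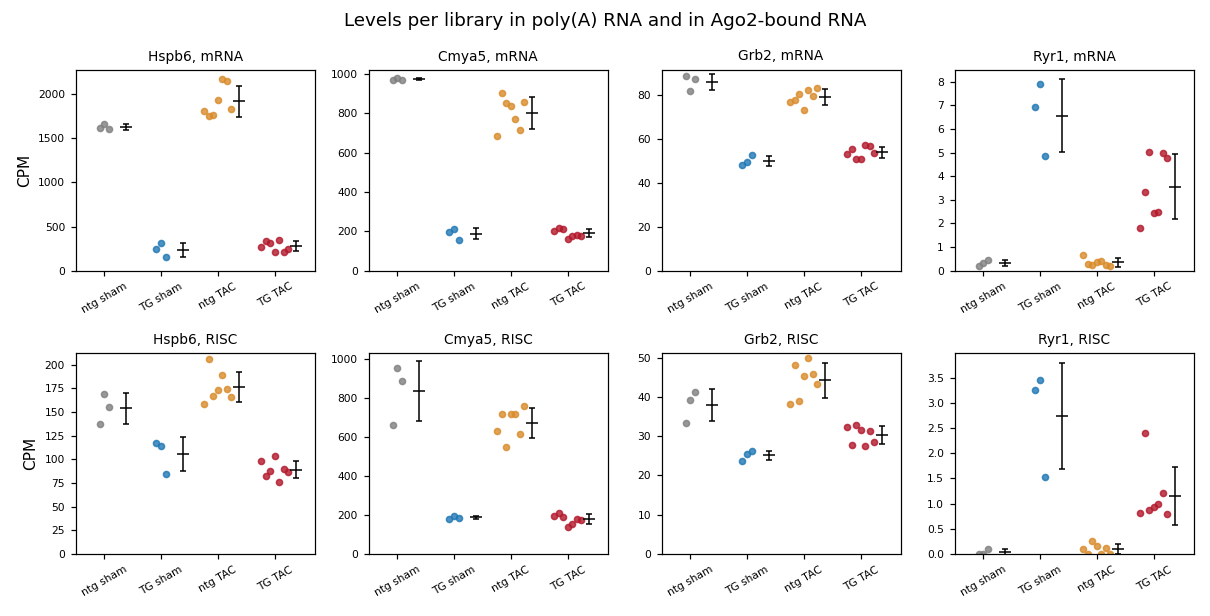
CPM of genes that differ between TG and ntg hearts, with each heart as a point. Cmya5 mRNA lies at 975 ± 6.34 CPM in ntg sham and 188 ± 29.1 CPM in TG sham hearts.

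Under pressure overload the transgene changed many of the same genes in the same direction. The loss of Hspb6 and Cmya5 was about as large as at rest. The glycolysis gene Pfkl was higher, while the interferon response gene Rsad2 and the macrophage genes Lyz2 and Cd68 were lower than in ntg hearts. In mRNA of TAC hearts 1915 genes were higher and 1669 lower in TG than in ntg.

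Hspb6 (chromosome 7, 30553302 to 30555439, plus strand) stood at 1920 ± 177 CPM in ntg TAC and 275 ± 57.8 CPM in TG TAC hearts (n = 7 each), a log2 fold change of -2.80 (SE 0.14, adjusted p = 3.29e-11). Cmya5, chosen here after its values were seen, was at -2.08 (SE 0.08, adjusted p = 1.17e-14). Ryr1 rose from 0.344 ± 0.17 to 3.55 ± 1.36 CPM (log2 fold change 3.38, SE 0.3, adjusted p = 1.39e-08). Slc24a2, a potassium-dependent sodium/calcium exchanger (chromosome 4, 86983126 to 87230540, minus strand), rose from 4.92 ± 1.49 to 27.2 ± 3.96 CPM (log2 fold change 2.46, SE 0.15, adjusted p = 2.65e-10). Pcbd1, a cofactor-recycling enzyme that also binds a transcription factor, rose by 2.4 (SE 0.2, adjusted p = 3.98e-09). Myh8, the perinatal myosin of skeletal muscle, rose by 2.57 (SE 0.29, adjusted p = 5.19e-07). The phosphodiesterase gene Pde11a fell by 2.68 (SE 0.23, adjusted p = 7.53e-09), the cadherin gene Cdh22 fell by 2.64 (SE 0.29, adjusted p = 5.65e-07), and the fatty acid desaturase gene Scd4 fell by 2.33 (SE 0.22, adjusted p = 2.34e-08). Kcnip2 was at -0.75 (SE 0.08, adjusted p = 2.82e-07). Mybpc2, a myosin binding protein of fast skeletal muscle, fell by 0.71 (SE 0.09, adjusted p = 1.48e-06). Thbs4, an extracellular protein induced in stressed myocardium, stood at 28.7 CPM in ntg and 57.3 CPM in TG hearts (log2 fold change 1, SE 0.17, adjusted p = 0.000276). Pfkl, a phosphofructokinase subunit, rose by 0.34 (SE 0.06, adjusted p = 0.000238). The largest fold change, 5.18 (SE 1.42, adjusted p = 0.0131), was that of Bmp10, a growth factor of the atria, whose level ran from 0.227 to 161 CPM among TG TAC hearts; with the replicate number as a block it was 4.24 (adjusted p = 0.0884). These adjusted p values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

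Of 21 glycolysis genes 10 rose and 1 fell, also when adjusted over the list alone; camera adjusted p = 0.0123, and adjusted p = 0.502 with an estimated correlation. Of 19 interferon response genes 7 fell (9 adjusted over the list alone; camera adjusted p = 0.0123), with adjusted p = 0.694 with an estimated correlation. Rsad2, an antiviral enzyme, fell by 0.54 (SE 0.13, adjusted p = 0.0036, edgeR). Of 17 macrophage genes 8 fell (9 adjusted over the list alone), with camera adjusted p = 0.0096 and adjusted p = 0.502 with an estimated correlation. Lyz2, a lysozyme of macrophages, fell by 0.42 (SE 0.08, adjusted p = 0.000254), and Cd68, a lysosomal macrophage protein, fell by 0.42 (SE 0.08, adjusted p = 0.000532). Genes of other cell types fell too, with the same counts adjusted over the list alone: 5 of 12 endothelial genes (camera adjusted p = 0.237; adjusted p = 0.508 with an estimated correlation), 4 of 10 smooth muscle genes (0.111; 0.624), 3 of 10 fibroblast genes (0.14; 0.694) and 2 of 8 lymphocyte genes (0.353; 0.743). The 17 macrophage genes were also lower in TG at rest (4 called, 5 adjusted over the list alone, camera adjusted p = 0.0156; adjusted p = 0.499 with an estimated correlation). Of 22 adult contraction genes 5 fell and 2 rose, also when adjusted over the list alone (camera adjusted p = 0.0495; adjusted p = 0.508 with an estimated correlation).

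Sham and TAC hearts are separate animals, so the transgene effect was measured independently at rest and under load. In mRNA 925 genes were higher in TG in both operations, where 176 would be shared if the lists were independent, and 779 were lower in both, where 157 would be. 8 genes were called in opposite directions. Among genes called at rest 96.1% had the same sign under load, and their median ratio of the TAC to the sham fold change was 0.572, a ratio that choosing genes by their sham call lowers by itself. A test of the difference called 12 genes of 14141.

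**Figure D3:**
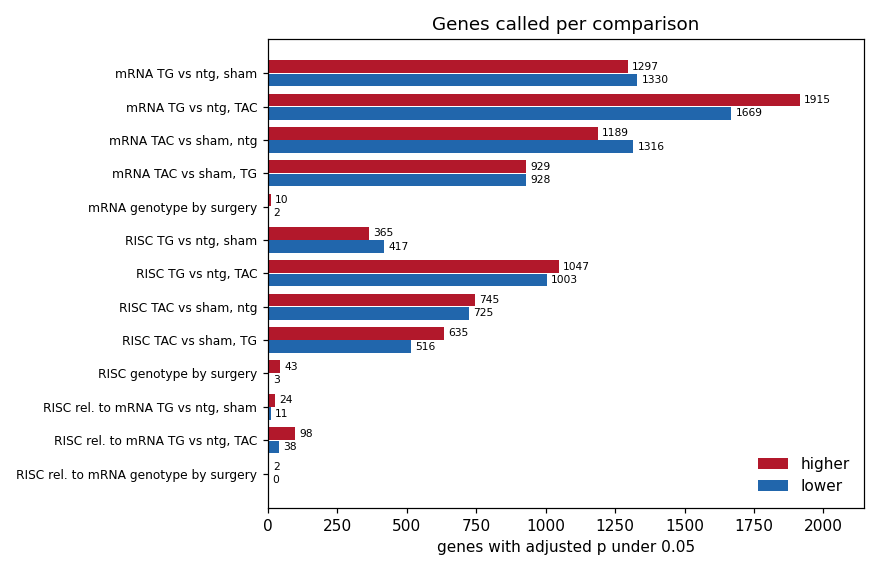
Genes called higher and lower in each comparison at adjusted p below 0.05. TG and ntg mRNA differ by 1297 higher and 1330 lower genes in sham, and by 1915 and 1669 in TAC hearts.

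Reported targets of miR-378 were looked at as a list of 10 genes fixed beforehand. The adaptor gene Grb2 was lower in TG hearts at rest and under load. Med13 passed the threshold under load, at the same fold change as at rest. Other members printed below moved less than Grb2.

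Grb2, which links receptor tyrosine kinases to Ras (chromosome 11, 115644144 to 115708597, minus strand), stood at 86.1 ± 3.5 CPM in ntg sham and 50.1 ± 2.43 CPM in TG sham mRNA, a log2 fold change of -0.78 (SE 0.07, adjusted p = 5.65e-08). In TAC hearts it went from 79.2 ± 3.5 to 54 ± 2.59 CPM (log2 fold change -0.55, SE 0.05, adjusted p = 4.95e-09). Med13, a subunit of the mediator complex (chromosome 11, 86265715 to 86357525, minus strand), fell by 0.25 (SE 0.07, adjusted p = 0.00725) in TAC hearts and was at -0.25 (SE 0.1, adjusted p = 0.0861) in sham hearts. Tusc2, a mitochondrial tumour suppressor, was at 0.14 (SE 0.05, adjusted p = 0.0371) in TAC hearts, and at 0.13 to 0.15 (adjusted p = 0.051 to 0.0708) without ntg TAC 1, 2, 3, 4 or 6 or TG TAC 2, 3, 5 or 7. In sham hearts the growth factor receptor gene Igf1r was at -0.22 (adjusted p = 0.192), the carnitine acetyltransferase gene Crat at -0.26 (adjusted p = 0.0673), the hedgehog inhibitor gene Sufu at 0.36 (adjusted p = 0.0788) and the kinase gene Pik3ca at -0.21 (adjusted p = 0.162). The scaffold gene Ksr1 at 0.03 (adjusted p = 0.893) and Tusc2 at -0.08 (adjusted p = 0.493) did not differ there. In mRNA 2 of the 10 fell at rest (4 fell and 1 rose adjusted over the list alone; camera adjusted p = 0.0193, and adjusted p = 0.245 with an estimated correlation). Under load 3 fell and 1 rose, also adjusted over the list alone (camera adjusted p = 0.0811; adjusted p = 0.502 with an estimated correlation). In RISC libraries Grb2 was at -0.6 (SE 0.12, adjusted p = 0.00203) in sham and -0.55 (SE 0.08, adjusted p = 1.08e-05) in TAC hearts. RISC Med13 was at -0.53 (SE 0.08, adjusted p = 2.07e-05) in TAC hearts. With the length slope of each library as a covariate, chosen after the data were seen, RISC Grb2 and Med13 in TAC hearts were at -0.49 (SE 0.14, adjusted p = 0.0789) and -0.41 (SE 0.14, adjusted p = 0.167). Relative to mRNA, RISC Grb2 was at 0.19 in sham and 0.01 in TAC hearts, so its Ago2-bound RNA fell about as its mRNA did. The host gene of the microRNA, Ppargc1b, a coactivator of mitochondrial genes (chromosome 18, 61298136 to 61400431, minus strand), was at -0.18 (SE 0.13, adjusted p = 0.366) in sham mRNA. Ago2, the protein whose antibody was used, is listed as Eif2c2 (chromosome 15, 73101625 to 73184947, minus strand) and was at 0.25 (SE 0.09, adjusted p = 0.0622) in sham and 0.16 (adjusted p = 0.0535) in TAC mRNA. These adjusted p values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

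RNA bound to Ago2 followed the mRNA changes of resting hearts in the main. Ryr1 was higher in the RISC of TG hearts, and Kcnip2 and Tnnc1 were lower. The complex I gene Ndufc1 was lower too, while the glycolysis gene Pkm was higher. In RISC of sham hearts 365 genes were higher and 417 lower in TG than in ntg, of 13451 tested.

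Ryr1 stood at 0.0317 ± 0.0549 CPM in ntg sham and 2.74 ± 1.06 CPM in TG sham RISC libraries (adjusted p = 1.46e-05). Erc2, a scaffold of the presynaptic active zone, stood at 0.119 ± 0.0436 and 2.97 ± 0.495 CPM (adjusted p = 1.31e-06). Rtn4r, a receptor that limits axon growth, fell by 2.67 (SE 0.27, adjusted p = 1.75e-08), and Wisp1 fell by 2.66 (SE 0.36, adjusted p = 5.93e-06). Kcnip2 (chromosome 19, 45792346 to 45816063, minus strand) went from 85.5 ± 10.4 to 33.9 ± 2.31 CPM, a log2 fold change of -1.33 (SE 0.14, adjusted p = 2.62e-08), close to its change in mRNA. Tnnc1, troponin C of cardiac muscle, fell by 0.58 (SE 0.11, adjusted p = 0.000868). Ndufc1, a complex I subunit, fell by 1.36 (SE 0.27, adjusted p = 0.00226). Pkm, pyruvate kinase of muscle, rose by 0.5 (SE 0.11, adjusted p = 0.00445). Cyr61, an immediate early matricellular gene, fell by 0.84 (SE 0.16, adjusted p = 0.00099), and Herpud1 fell by 0.99 (SE 0.15, adjusted p = 4.08e-05). Ppargc1b was at -0.51 (SE 0.14, adjusted p = 0.0218) in these libraries, and its call ended without ntg sham 2 (-0.4, adjusted p = 0.146), ntg sham 3 (-0.44, adjusted p = 0.114) or TG sham 3 (-0.38, adjusted p = 0.167) and with the adipocyte covariate (-0.43, adjusted p = 0.105). Of 22 adult contraction genes 8 fell and 1 rose (12 and 2 adjusted over the list alone; camera adjusted p = 3.71e-05), with adjusted p = 0.589 with an estimated correlation. Of 74 ribosomal protein genes 5 fell, also adjusted over the list alone (camera adjusted p = 2.49e-06; adjusted p = 0.749 with an estimated correlation). Of 59 oxidative phosphorylation genes 5 fell; adjusted over the list alone 12 fell and 2 rose (camera adjusted p = 0.000269; adjusted p = 0.749 with an estimated correlation). Of 20 glycolysis genes 3 rose; adjusted over the list alone 8 rose and 1 fell (camera adjusted p = 0.00329; adjusted p = 0.642 with an estimated correlation). Genes were tested with edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The number called was 782, and it was 517 without ntg sham 2, 441 without ntg sham 3, 495 without TG sham 1, 492 without TG sham 2 and 488 without TG sham 3.

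Under load short genes were higher in TG than ntg RISC. Hist1h4h, Rpl29, Atp5d and Gapdh were higher, and the small nucleolar RNA Snora3 showed the largest gain among named genes. The long muscle gene Cmya5 was lower. In RISC of TAC hearts 1047 genes were higher and 1003 lower in TG than in ntg.

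The median transcript length was 2098 bases among the higher and 4874 bases among the lower genes, and across all genes the fold change ran against length (Spearman correlation -0.305). The small nucleolar RNA Snora3, which lies inside the ribosomal protein gene Rpl27a (chromosome 7, 109520132 to 109520251, plus strand), stood at 0.0532 ± 0.0943 CPM in ntg TAC and 2.35 ± 1.61 CPM in TG TAC libraries (adjusted p = 2.96e-06). Hist1h4h, a histone H4 gene, rose from 1.67 ± 1.15 to 6.16 ± 1.5 CPM (log2 fold change 1.81, SE 0.26, adjusted p = 1.96e-05). Gapdh, a glycolytic enzyme, rose by 0.63 (SE 0.08, adjusted p = 9.26e-07). Atp5d, an ATP synthase subunit, rose by 0.62 (SE 0.09, adjusted p = 1.14e-05), and Rpl29, a protein of the large ribosomal subunit, rose by 0.63 (SE 0.11, adjusted p = 7.4e-05). Cmya5 (chromosome 13, 93040715 to 93144724, minus strand) went from 672 ± 75.5 to 177 ± 25 CPM, a log2 fold change of -1.92 (SE 0.09, adjusted p = 2.14e-17). Kcnip2 was at -0.72 (SE 0.09, adjusted p = 6.67e-07). Of 23 histone genes 8 rose (12 adjusted over the list alone; camera adjusted p = 6.75e-08), and the call was kept with adjusted p = 0.039 with an estimated correlation. Among 59 oxidative phosphorylation genes 20 rose; adjusted over the list alone 23 rose and 1 fell (camera adjusted p = 2.83e-06; adjusted p = 0.665 with an estimated correlation). Of 74 ribosomal protein genes 14 rose (19 adjusted over the list alone; camera adjusted p = 2.83e-06; adjusted p = 0.676 with an estimated correlation). Of 20 glycolysis genes 11 rose (12 adjusted over the list alone; camera adjusted p = 3.83e-07; adjusted p = 0.109 with an estimated correlation). Adjusted p values of genes come from edgeR's quasi-likelihood test. With the length slope, which separates the genotypes, as a covariate 172 genes were called. Gapdh was at 0.39 (SE 0.13, adjusted p = 0.136) and Rpl29 at 0.11 (SE 0.15, adjusted p = 0.837). Atp5d was at 0.24 (SE 0.14, adjusted p = 0.491) and Hist1h4h at 1.45 (SE 0.42, adjusted p = 0.0797). Cmya5, Kcnip2 and Snora3 kept their calls. Without the near-identical RISC libraries TG TAC 3 and TG TAC 7 the mean of the ribosomal list went from 0.294 to 0.13.

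**Figure D4:**
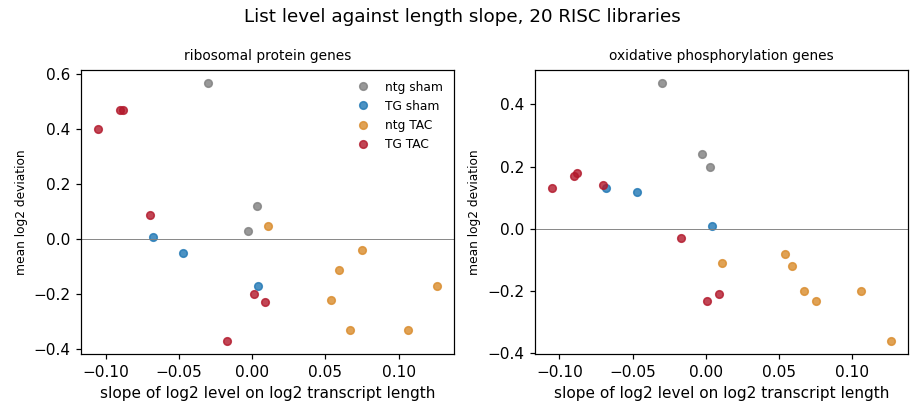
Slope of expression on transcript length in each RISC library. The mean slope is 0.0711 ± 0.0372 in ntg TAC and -0.0514 ± 0.0477 in TG TAC libraries.

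The transgene effect in RISC at rest recurred under load for many genes. It was higher in both operations for 232 genes, where 28.4 would be shared if the lists were independent, and lower in both for 224, where 31.1 would be; 11 genes were called in opposite directions. RISC and mRNA of the same hearts moved together, with a Pearson correlation of TG fold changes of 0.553 in sham and 0.595 in TAC hearts over 13273 genes. In sham hearts 236 genes were higher in both kinds of library and 232 lower in both. In TAC hearts the counts were 584 and 561, and 17 genes were higher in RISC but lower in mRNA. Grpel1, a co-chaperone of mitochondrial protein import, was among the 17: it was at -0.17 (SE 0.06, adjusted p = 0.0299, edgeR) in mRNA and 0.85 (SE 0.08, adjusted p = 3.64e-09) in RISC. Grpel1 was chosen after its values were seen.

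RISC relative to mRNA asks whether a message changed more in RISC than in mRNA. No library is a control immunoprecipitation, so unbound RNA carried over cannot be excluded. At rest few genes differed, and Hspb6 was higher. In sham hearts 24 genes were higher and 11 lower in TG than in ntg, of 14372 tested.

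Hspb6 (chromosome 7, 30553302 to 30555439, plus strand) was at 2.24 (SE 0.25, adjusted p = 3.16e-07) relative to mRNA, since its RISC level went only from 154 ± 16.1 to 106 ± 18.1 CPM while its mRNA went from 1630 ± 34.7 to 235 ± 79.9 CPM. Fdft1, squalene synthase of the cholesterol pathway, was at 1.35 (SE 0.22, adjusted p = 0.000676); its mRNA went from 42.1 ± 1.09 to 19.3 ± 2.55 CPM and its RISC from 6.65 to 7.83 CPM. Mfsd4, a solute transporter, was at -1.37 (SE 0.19, adjusted p = 1.09e-05). Ldha, lactate dehydrogenase of muscle, was at 0.73 (SE 0.14, adjusted p = 0.00445), a call that ended without ntg sham 2 (0.69, adjusted p = 0.0556) and without TG sham 3 (0.59, adjusted p = 0.131). Cmya5 was at 0.22 (adjusted p = 0.759), so its RISC fell with its mRNA. Of the 10 reported miR-378 targets all stood at an adjusted p of 0.267 or above. Fibroblast genes were higher as a list (camera adjusted p = 0.00764; adjusted p = 0.849 with an estimated correlation), with 0 of 10 called among all genes or adjusted over the list alone by edgeR. Their median was -0.445 in mRNA, where 4 fell, and -0.016 in RISC. Genes were tested with edgeR's quasi-likelihood test. With each heart's mRNA and RISC library as a block 68 genes were called in place of 35, and DESeq2 called 122. The count was 17 without ntg sham 1, 14 without ntg sham 2, 19 without ntg sham 3, 12 without TG sham 1 and 8 without TG sham 3.

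Under load Hspb6 was again higher relative to mRNA, Mfsd4 again lower and Atp5c1 higher. In TAC hearts 98 genes were higher and 38 lower in TG than in ntg.

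Hspb6 was at 1.81 (SE 0.16, adjusted p = 3.73e-10) relative to mRNA. Tmem192, a lysosomal membrane protein (chromosome 8, 64947185 to 64969037, plus strand), was at 1.17 (SE 0.18, adjusted p = 6.38e-05), Mfsd4 at -0.92 (SE 0.12, adjusted p = 2.94e-06) and Slc24a2 at -1.06 (SE 0.2, adjusted p = 0.00258). Hist1h4h was at 2.36 (SE 0.34, adjusted p = 3.88e-05). Myl2, the ventricular myosin light chain, was at 0.72 (SE 0.14, adjusted p = 0.00204). Atp5c1, an ATP synthase subunit, was at 0.7 (SE 0.12, adjusted p = 0.000221); its mRNA went from 966 ± 81.8 to 762 ± 100 CPM and its RISC from 135 ± 15.9 to 174 ± 14.7 CPM. Gapdh was at 0.55 (SE 0.1, adjusted p = 0.000798) and Ldha at 0.49 (SE 0.09, adjusted p = 0.0013). Of 77 ribosomal protein genes 3 rose (11 adjusted over the list alone; camera adjusted p = 3.45e-11; adjusted p = 0.601 with an estimated correlation). Of 59 oxidative phosphorylation genes 2 rose (8 adjusted over the list alone; camera adjusted p = 3.01e-06; adjusted p = 0.601 with an estimated correlation). Of 27 histone genes 2 rose, also adjusted over the list alone (camera adjusted p = 0.00245, 0.571 with an estimated correlation). Polyadenylated RNA may miss these. The higher genes had a median length of 1451 bases and the lower genes 5125 bases, and the length covariate was not used here. Of the reported miR-378 targets the lowest adjusted p was that of Crat (0.145). The test for genes was edgeR's quasi-likelihood test. 15 genes were higher at rest and under load, where 0.164 would be shared if the lists were independent, and 2 were lower in both. With each heart as a block 236 genes were called in place of 136, and DESeq2 called 329.

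Pressure overload in ntg hearts raised skeletal actin, slow myosin, the stress gene Ankrd1 and matrix genes such as Sparc. Ppargc1a, Hadhb and the calcium pump gene Atp2a2 were lower, while the natriuretic peptide genes were not called. In mRNA 1189 genes were higher and 1316 lower in ntg TAC than in ntg sham hearts. These hearts also differ in sex-linked genes: Xist was at -6.28 (SE 0.17, adjusted p = 4.37e-16, edgeR).

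Acta1, the skeletal alpha-actin (chromosome 8, 123891758 to 123894775, minus strand), went from 700 ± 146 CPM in ntg sham to 3740 ± 719 CPM in ntg TAC hearts, a log2 fold change of 2.42 (SE 0.39, adjusted p = 0.000463). Ankrd1, a stress-responsive protein of the sarcomere (chromosome 19, 36111965 to 36119844, minus strand), rose from 2320 ± 264 to 6780 ± 950 CPM (log2 fold change 1.54, SE 0.17, adjusted p = 1.98e-06). Mybpc2 rose by 1.47 (SE 0.12, adjusted p = 3.24e-08). Myh7, the slow myosin heavy chain, rose by 0.68 (SE 0.14, adjusted p = 0.0014), and Myh6, the fast one of the adult mouse ventricle, fell by 0.38 (SE 0.09, adjusted p = 0.00667). The natriuretic peptide genes Nppa, at 0.55 (SE 0.78, adjusted p = 0.684), and Nppb, at 0.33 (SE 0.24, adjusted p = 0.37), did not differ. Col1a1, a fibrillar collagen (chromosome 11, 94936270 to 94951856, plus strand), went from 178 ± 43.9 to 492 ± 100 CPM (log2 fold change 1.47, SE 0.31, adjusted p = 0.00338). Postn, a matrix protein of activated fibroblasts, rose by 1.77 (SE 0.39, adjusted p = 0.00448), and Sparc, a collagen-binding matrix protein, rose by 1.16 (SE 0.14, adjusted p = 1e-05). Atp2a2, the calcium pump of the sarcoplasmic reticulum, fell by 0.58 (SE 0.09, adjusted p = 9.3e-05). Ppargc1a, the coactivator of mitochondrial biogenesis (chromosome 5, 51454249 to 51553921, minus strand), fell from 351 ± 39.8 to 80.1 ± 3.98 CPM (log2 fold change -2.13, SE 0.1, adjusted p = 9.53e-13). Hadhb, of mitochondrial beta-oxidation, fell by 0.62 (SE 0.11, adjusted p = 0.00043), and Ndufs1, of complex I, fell by 0.49 (SE 0.08, adjusted p = 0.000108). Ccna2, a cyclin, rose by 1.55 (SE 0.28, adjusted p = 0.000562), and the interferon-induced gene Oas1a rose by 1.99 (SE 0.37, adjusted p = 0.000684). Adjusted p values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

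Of 35 matrix genes 24 rose (26 adjusted over the list alone; camera adjusted p = 1.54e-17; adjusted p = 0.172 with an estimated correlation). Of 22 adult contraction genes 15 fell and 1 rose (17 and 1 adjusted over the list alone; camera adjusted p = 1.29e-08), and this call was kept with adjusted p = 0.0347 with an estimated correlation. Among 59 oxidative phosphorylation genes 28 fell (39 adjusted over the list alone; camera adjusted p = 1.26e-13; adjusted p = 0.172 with an estimated correlation). Of 27 fatty acid oxidation genes 19 fell (21 adjusted over the list alone; camera adjusted p = 4.75e-12; adjusted p = 0.172 with an estimated correlation). Of 16 hypertrophy and fetal genes 5 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.00153; adjusted p = 0.172 with an estimated correlation). Of 11 proliferation genes 9 rose (10 adjusted over the list alone; camera adjusted p = 3.56e-08; adjusted p = 0.0683 with an estimated correlation). Of 19 interferon genes 6 rose, also adjusted over the list alone (camera adjusted p = 1.64e-05; adjusted p = 0.215 with an estimated correlation). All of the 4 red blood cell genes rose, also adjusted over the list alone (camera adjusted p = 0.003; adjusted p = 0.215 with an estimated correlation; median 1.43). Of 17 macrophage genes 3 rose, also adjusted over the list alone (camera adjusted p = 0.0224; adjusted p = 0.336 with an estimated correlation). Adipocyte genes fell as a list (3 called, 8 adjusted over the list alone; camera adjusted p = 8.21e-05; adjusted p = 0.215 with an estimated correlation), and all of these genes were compared between hearts that differ in Xist and Y-linked RNA. The number of genes called was 2505; it was 1473 without ntg sham 1, 1484 without ntg sham 2 and 768 with the adipocyte covariate. With that covariate Myh7 was at 0.58 (SE 0.19, adjusted p = 0.0768), Myh6 at -0.32 (SE 0.14, adjusted p = 0.178), Col1a1 at 1.27 (SE 0.42, adjusted p = 0.0866) and Postn at 1.78 (SE 0.52, adjusted p = 0.0594), while Acta1, Ankrd1, Mybpc2, Sparc, Atp2a2 and Ppargc1a kept their calls.

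**Figure D5:**
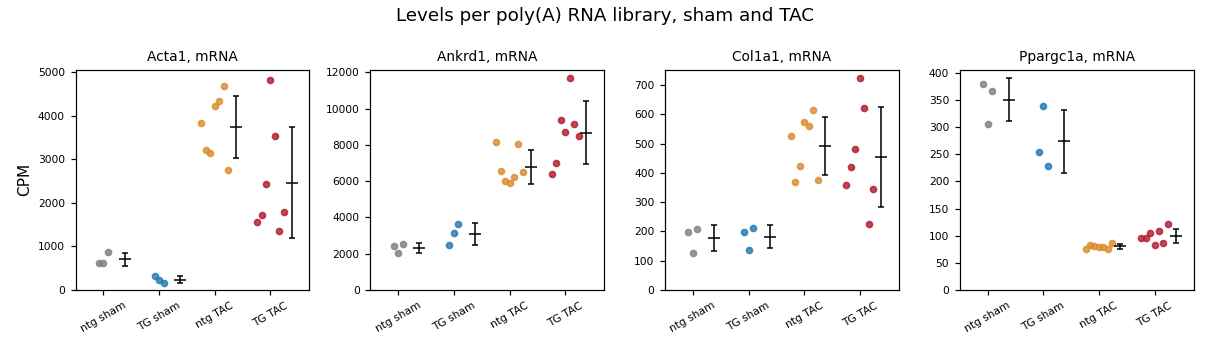
CPM of genes that differ between TAC and sham hearts, with each heart as a point. Acta1 mRNA lies at 700 ± 146 CPM in ntg sham and 3740 ± 719 CPM in ntg TAC hearts.

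In TG hearts overload raised Acta1, Ankrd1 and Sparc and lowered Ppargc1a and Sdha. In mRNA 929 genes were higher and 928 lower in TG TAC than in TG sham hearts. Xist was at -6.46 in this comparison too, so sex-linked RNA differs here as in ntg hearts.

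Acta1 (chromosome 8, 123891758 to 123894775, minus strand) rose from 237 ± 79.8 to 2460 ± 1270 CPM, a log2 fold change of 3.37 (SE 0.41, adjusted p = 0.000113). Ankrd1 rose by 1.5 (SE 0.16, adjusted p = 6.46e-06), Postn by 2.16 (SE 0.4, adjusted p = 0.00267), Col1a1 by 1.32 (SE 0.31, adjusted p = 0.0101) and Sparc by 1.02 (SE 0.14, adjusted p = 9.62e-05). Mybpc2 rose by 0.9 (SE 0.12, adjusted p = 3.65e-05) and Myh7 by 0.45 (SE 0.14, adjusted p = 0.0301). Atp2a2 fell by 0.31 (SE 0.09, adjusted p = 0.0214) and Ppargc1a fell by 1.46 (SE 0.1, adjusted p = 1.53e-09). Sdha, of complex II, fell by 0.31 (SE 0.07, adjusted p = 0.00526), and Arntl, a transcription factor of the circadian clock, fell by 2.14 (SE 0.39, adjusted p = 0.00208). Nppa was at 2.17 (SE 0.86, adjusted p = 0.107), Nppb at 0.24 (adjusted p = 0.543) and Myh6 at -0.18 (adjusted p = 0.213). Of 35 matrix genes 26 rose (30 adjusted over the list alone; camera adjusted p = 5.03e-22; adjusted p = 0.24 with an estimated correlation). Of 16 hypertrophy genes 6 rose; adjusted over the list alone 8 rose and 1 fell (camera adjusted p = 2.65e-07; adjusted p = 0.131 with an estimated correlation). Of 59 oxidative phosphorylation genes 15 fell (23 adjusted over the list alone; camera adjusted p = 2.47e-12; adjusted p = 0.24 with an estimated correlation). Of 27 fatty acid oxidation genes 7 fell (17 adjusted over the list alone; camera adjusted p = 4.6e-05; adjusted p = 0.476 with an estimated correlation). Of 22 adult contraction genes 5 fell and 1 rose (9 and 1 adjusted over the list alone; camera adjusted p = 0.0301; adjusted p = 0.353 with an estimated correlation). Of 10 fibroblast genes 3 rose (5 adjusted over the list alone; camera adjusted p = 0.00129; adjusted p = 0.24 with an estimated correlation). Of 17 macrophage genes 4 rose and 1 fell (7 and 2 adjusted over the list alone; camera adjusted p = 0.00522; adjusted p = 0.35 with an estimated correlation). Of 11 proliferation genes 4 rose (6 adjusted over the list alone; camera adjusted p = 0.000345; adjusted p = 0.24 with an estimated correlation). Gene tests are edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. In place of 1857 genes, 1098 were called without TG sham 1 (983 of them shared), 1020 without TG sham 2 (928 shared) and 1009 in a fit of these 2 groups alone (978 shared). The call of Myh7 ended without TG sham 1 (0.36, adjusted p = 0.157), without TG sham 2 (0.37, adjusted p = 0.151) and in that fit (0.46, adjusted p = 0.102). That of Atp2a2 ended in the same 3 (-0.33, adjusted p = 0.0571; -0.25, adjusted p = 0.131; -0.31, adjusted p = 0.0836), and that of Col1a1 without TG sham 2 (1.15, adjusted p = 0.0615).

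RNA bound to Ago2 differed between ntg TAC and ntg sham hearts as well. RNA of Acta1, Sparc and Myh7 rose, and RNA of Ppargc1a and Hspa5 fell. In RISC 745 genes were higher and 725 lower in ntg TAC than in ntg sham hearts. Ddx3y, a Y-linked helicase (chromosome Y, 1260715 to 1286613, minus strand), was at 6.78, since these groups differ in sex-linked RNA.

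Acta1 (chromosome 8, 123891758 to 123894775, minus strand) rose from 127 ± 41.3 to 500 ± 135 CPM, a log2 fold change of 1.97 (SE 0.38, adjusted p = 0.00288). Ankrd1 rose by 1.45 (SE 0.13, adjusted p = 3.68e-10), Postn by 1.81 (SE 0.35, adjusted p = 0.00308), Col1a1 by 1.51 (SE 0.33, adjusted p = 0.00781), Sparc by 0.95 (SE 0.13, adjusted p = 8.97e-06) and Myh7 by 1.09 (SE 0.15, adjusted p = 2.1e-05). Atp2a2 fell by 0.63 (SE 0.11, adjusted p = 0.000134). Tnni3, troponin I of cardiac muscle, fell by 0.8 (SE 0.11, adjusted p = 1.05e-05). Ppargc1a fell by 1.98 (SE 0.12, adjusted p = 1.96e-14). Agt, the angiotensin precursor, fell by 3.4 (SE 0.36, adjusted p = 4.44e-08), and Hspa5, the chaperone of the endoplasmic reticulum, fell by 0.9 (SE 0.13, adjusted p = 1.15e-05). Nppa was at -0.2 (adjusted p = 0.826) and Nppb at -0.26 (adjusted p = 0.588). Among 59 oxidative phosphorylation genes 42 fell (48 adjusted over the list alone; camera adjusted p = 8.62e-28; adjusted p = 0.0982 with an estimated correlation). Of 35 matrix genes 20 rose (25 adjusted over the list alone; camera adjusted p = 4.44e-18; adjusted p = 0.201 with an estimated correlation). Of 74 ribosomal protein genes 11 fell (14 adjusted over the list alone; camera adjusted p = 5.29e-12; adjusted p = 0.347 with an estimated correlation). Of 20 heat shock and unfolded protein response genes 5 fell (6 adjusted over the list alone; camera adjusted p = 0.000155; adjusted p = 0.201 with an estimated correlation). Of 15 hypertrophy genes 5 rose and 1 fell; camera gave a higher list with adjusted p = 0.00363, and adjusted p = 0.201 with an estimated correlation, while the median fold change was -0.0154 and the mean 0.29. Genes were tested with edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Fold changes ran with transcript length here (Spearman correlation 0.17). In place of 1470 genes, 295 were called with the length covariate (285 of them shared), 730 without ntg sham 1 (686 shared) and 954 without ntg sham 2 (867 shared); Acta1, Ankrd1, Postn, Sparc, Myh7, Atp2a2 and Ppargc1a kept their calls, and the call of Col1a1 ended with the covariate (1.1, adjusted p = 0.126) and without ntg sham 2 (1.32, adjusted p = 0.053).

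In TG hearts RISC RNA of Acta1, Ankrd1 and Sparc rose again under overload. RNA of Ppargc1a, Nfil3 and Arntl fell. In RISC 635 genes were higher and 516 lower in TG TAC than in TG sham hearts, which differ in sex-linked RNA as well.

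Acta1 (chromosome 8, 123891758 to 123894775, minus strand) rose from 48.7 ± 8.27 to 398 ± 189 CPM, a log2 fold change of 3.03 (SE 0.4, adjusted p = 0.000292). Ankrd1 rose by 1.13 (SE 0.12, adjusted p = 1.36e-07), Col1a1 by 1.62 (SE 0.33, adjusted p = 0.00669), Sparc by 0.88 (SE 0.13, adjusted p = 5.09e-05) and Postn by 1.49 (SE 0.34, adjusted p = 0.0118). Myh7 was at 0.6 (SE 0.15, adjusted p = 0.00965). Ppargc1a fell by 1.65 (SE 0.12, adjusted p = 3.98e-12), Atp2a2 by 0.62 (SE 0.11, adjusted p = 0.000269) and Hspa5 by 0.73 (SE 0.13, adjusted p = 0.000351). Nfil3, a repressor in the circadian clock, fell by 1.7 (SE 0.2, adjusted p = 3.54e-07), and Arntl fell by 2.07 (SE 0.43, adjusted p = 0.00561). Nppa was at 0.9 (adjusted p = 0.236), Nppb at 0.02 (adjusted p = 0.975) and Myh6 at -0.32 (adjusted p = 0.0667). Of 35 matrix genes 22 rose (32 adjusted over the list alone; camera adjusted p = 8.93e-22; adjusted p = 0.293 with an estimated correlation). Of 27 fatty acid oxidation genes 5 fell (8 adjusted over the list alone; camera adjusted p = 0.000224; adjusted p = 0.354 with an estimated correlation). Adjusted p values of genes come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. In place of 1151 genes, 669 were called without TG sham 1, 510 without TG sham 2 and 610 without TG sham 3. The call of Postn ended without TG sham 1 (1.38, adjusted p = 0.0666) and without TG sham 2 (1.43, adjusted p = 0.0666), and that of Myh7 without TG sham 2 (0.59, adjusted p = 0.0569) and without TG sham 3 (0.62, adjusted p = 0.0514).

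The last comparison asks whether the transgene changes the response to overload. In mRNA few genes were called, among them Plin4 and Elovl6, whose gap between ntg and TG hearts was narrower under load than at rest. The same comparison also sets sham hearts with Xist RNA against TAC hearts with Y-linked RNA, and hearts with different adipocyte gene levels. In mRNA 10 genes had a higher and 2 a lower transgene effect under load than at rest.

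Plin4, a coat protein of lipid droplets (chromosome 17, 56100591 to 56109802, minus strand), had a transgene effect of -1.53 at rest and -0.4 under load, a difference of 1.13 (SE 0.15, adjusted p = 0.00127). Its mRNA stood at 504 ± 57.6, 174 ± 13.2, 259 ± 28.9 and 196 ± 24.4 CPM in ntg sham, TG sham, ntg TAC and TG TAC hearts. Elovl6, a fatty acid elongase (chromosome 3, 129532386 to 129638493, plus strand), differed by 2.27 (SE 0.42, adjusted p = 0.0258). Its call ended without ntg sham 1 (2.39, adjusted p = 0.0553), ntg sham 3 (1.96, adjusted p = 0.151), TG sham 1 (2.31, adjusted p = 0.0946), TG sham 3 (2.02, adjusted p = 0.0677), ntg TAC 6 (2.26, adjusted p = 0.0506) or TG TAC 3 (2.24, adjusted p = 0.051). The citrate carrier gene Slc25a1 differed by 1.31 (SE 0.24, adjusted p = 0.0258), a call that ended without any single sham heart other than ntg sham 2 (1.07 to 1.39, adjusted p = 0.0552 to 0.166). Camera called 10 lists, with the adipocyte list at adjusted p = 8.76e-08 and adjusted p = 0.317 with an estimated correlation; 3 of its members were called adjusted over the list alone, and 0 among all genes by edgeR. For the transgene effects of the other 9 lists camera's adjusted p precedes that with an estimated correlation. Effects were higher under load for ribosomal (5.17e-06, 0.552), adult contraction (5.32e-05, 0.244) and fatty acid oxidation lists (0.000762, 0.536). The same held for atrial (0.00402, 0.525), fibroblast (0.0171, 0.483) and glycolysis lists (0.0249, 0.447). They were lower for interferon (0.00218, 0.535), proliferation (0.00402, 0.447) and histone lists (0.0171, 0.447). Of their members 0 were called among all genes by edgeR, and 1 adjusted over the list alone, in adult contraction. Values of adjusted p for genes are those of edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. With the adipocyte covariate 1 gene was called in place of 12, with Plin4 at 0.9 (SE 0.17, adjusted p = 0.114), Elovl6 at 1.56 (SE 0.47, adjusted p = 0.603) and Slc25a1 at 0.89 (SE 0.26, adjusted p = 0.55), and DESeq2 called 70. The count was 1 without ntg sham 1, 22 without ntg sham 2, 1 without ntg sham 3, 4 without TG sham 1 and 20 without ntg TAC 5.

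In RISC the transgene effect on Cox17, Ndufc1 and Plin4 differed between rest and load. Cox17 and Ndufc1 are short genes, and RISC libraries of TAC hearts differ in length slope and, as above, in sex-linked RNA. In RISC 43 genes had a higher and 3 a lower transgene effect under load.

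Cox17, a copper chaperone for cytochrome c oxidase (chromosome 16, 38346999 to 38352763, plus strand), had an effect of -1.06 at rest and 0.52 under load, a difference of 1.57 (SE 0.21, adjusted p = 0.000101). Its RISC level was 18.6 ± 3.52, 8.94 ± 2.07, 9.42 ± 0.936 and 13.4 ± 1.8 CPM in ntg sham, TG sham, ntg TAC and TG TAC hearts. Plin4 differed by 1.18 (SE 0.16, adjusted p = 0.000115), close to its difference in mRNA. Ndufc1 differed by 1.88 (SE 0.32, adjusted p = 0.00654). Of 74 ribosomal protein genes 3 had higher effects (21 adjusted over the list alone, camera adjusted p = 4.78e-24, 0.447 with an estimated correlation). Of 59 oxidative phosphorylation genes 6 did (26 adjusted over the list alone, camera adjusted p = 1.12e-18, 0.447 with an estimated correlation). Genes with a higher effect had a median length of 1051 bases and those with a lower effect 4931 bases. The test for genes was edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. In place of 46 genes, 9 were called with the length covariate (8 of them shared), 19 with the adipocyte covariate (17 shared) and 130 with DESeq2 (45 shared). The count was 21 without ntg sham 3, 5 without TG sham 2 and 12 without TG sham 3, and the call of Ndufc1 ended without TG sham 2 (1.83, adjusted p = 0.0627) and with the length covariate (1.47, adjusted p = 0.094).

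Relative to mRNA the transgene effect differed between rest and load for 2 genes. Gm13889, an uncharacterized gene (chromosome 2, 93955810 to 93957100, minus strand), differed by 2.12 (SE 0.42, adjusted p = 0.0495), with an effect of -1.79 at rest and 0.33 under load. Ptger1, a prostaglandin E receptor (chromosome 8, 83666640 to 83670103, plus strand), differed by 1.88 (SE 0.36, adjusted p = 0.0495), with -1.52 at rest and 0.35 under load. The ribosomal list had camera adjusted p = 5.54e-08 and adjusted p = 0.898 with an estimated correlation, with 3 members called adjusted over the list alone. The oxidative phosphorylation list had camera adjusted p = 5.99e-08 and adjusted p = 0.898 with an estimated correlation, with 8 called adjusted over the list alone. Gene tests are edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. With each heart as a block 5 genes were called and with DESeq2 26. With no filter on low counts the count was 1, without the shallow libraries ntg TAC 5 and ntg TAC 6 it was 0 (2 with them), and with RISC TG TAC 3 and TG TAC 7 summed it was 0. The count was also 0 without ntg sham 1, ntg sham 2, ntg sham 3, TG sham 1, TG sham 3, ntg TAC 2, ntg TAC 3, ntg TAC 4, ntg TAC 6, TG TAC 1, TG TAC 2, TG TAC 3 or TG TAC 7. Over these left-out hearts Gm13889 was at 1.98 to 2.22 and Ptger1 at 1.7 to 1.98 (adjusted p = 0.0543 to 0.29 for each). The count was 1 without ntg TAC 1 (Gm13889 adjusted p = 0.0565) or TG TAC 6 (0.0656), 4 without TG sham 2 or ntg TAC 7, 7 without TG TAC 4 and 9 without ntg TAC 5, against 1123 genes at unadjusted p below 0.05 by edgeR.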

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

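The tests of sex-linked genes, adipocyte genes and libraries, the covariates, and the tests with other libraries left out were chosen after the results were seen. For the comparisons with genes matched on length and for the other splits of the samples, the outcomes that would decide were written down before the results were seen.

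Among groups of 7, 1 of 84 tests found a value far from the others, where chance gives 4.2. The mRNA library TG TAC 7 held 25.5 M gene counts, while the other TG TAC libraries held 13.3 to 17.6 M.

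The transgene effect differed between TAC and sham hearts, by edgeR's test of the difference, for these mRNAs: Elovl6 (log2 difference 2.27), Slc25a1 (1.31), Plin4 (1.13), Fmo2 (0.96), Psd3 (0.91), Pdlim3 (0.85), Pcdh12 (-0.75) and Ets2 (-0.5). Leaving out single libraries ended the calls of 7 of these 8, all but that of Plin4. In RISC the genes with the most different effects were 9130019P16Rik (2.46), Rplp2 (1.89), Ndufc1 (1.88), D8Ertd738e (1.63), Romo1 (1.62), Cox17 (1.57), Mtx3 (-0.84), Rasgrp3 (-0.8) and Bcl6b (-0.71); without TG sham 2 the calls of 8 of these 9 ended, all but that of Cox17. For RISC relative to mRNA they were Gm13889 (2.12) and Ptger1 (1.88), and both calls ended without single hearts. Reads without a unique alignment, which the comparisons do not use, made up 4.79% (SD 0.766) of alignments in TG TAC RISC and 3.27% (SD 0.231) in ntg TAC RISC libraries. All 3432 regroupings of the 14 libraries give an exact two-sided permutation p of 0.000583, adjusted over 4 such tests p = 0.00233.

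Sham and TAC hearts differ in sex-linked RNA, while the labels give every mouse as male. In 20 of 20 mRNA libraries Xist was above and the Y-linked genes below 20 CPM in sham, or the reverse in TAC. Over all 40 libraries this held for 34, since Xist lay under 20 CPM in the 6 sham RISC libraries, and the test was limited to mRNA after that was seen. An exchange of single libraries between operations is excluded, since 0 of 40 libraries lay on the side of the other operation. Female sham and male TAC hearts may be the source; how far sex adds to the TAC genes cannot be told apart from surgery, because the groups coincide, and 3.31% of the ntg mRNA calls lay on X or Y, against 3.25% of the tested genes.

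Adipocyte genes were high in ntg sham mRNA, and the 12 interaction calls in mRNA include Elovl6, Slc25a1, Acly and Plin4, picked after their values were seen and not tested as a group. Adipose tissue in the ntg sham sections may be the source of the adipocyte genes: of 10 other fat cell genes, outside that list, 9 (all but Aqp7) had every ntg sham library above every TG sham library, as 17.6% of all tested genes did. A smaller share of cardiomyocytes as the whole cause is argued against, since other cell types moved far less than the adipocyte list (median fold change -3.26): endothelial genes stood at -0.05, smooth muscle at -0.242, macrophage at -0.249, fibroblast at -0.445, lymphocyte at -0.51 and mesothelial genes at -0.82, and as a part of the cause it stays open. Whether fat is the whole cause of the 12 interaction calls cannot be told, since the adipocyte covariate separates the sham genotypes. With it 0 of the 12 shrank to under 0.5 of its size, yet calls ended. The fold shrank for Elovl6, from 2.27 (SE 0.42) to 1.56 (SE 0.47), and Slc25a1, from 1.31 (SE 0.24) to 0.89 (SE 0.26). So it did for Acly, from 0.78 (SE 0.14) to 0.53 (SE 0.15), and Plin4, from 1.13 (SE 0.15) to 0.9 (SE 0.17). For others such as Lrrc10, from 0.74 (SE 0.12) to 0.81 (SE 0.15), the standard error grew. Fat as a cause stays open, and so do, untested, a transgene effect on fat genes or heart fat and the sex of the hearts.

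In TG RISC libraries after TAC 14 of 74 ribosomal and 20 of 59 oxidative phosphorylation genes rose (19 and 23 adjusted over the list alone), with list tests at adjusted p = 0.676 and 0.665 with an estimated correlation. Transcript length may account for the higher means: among 10000 lists matched on length and level the list means lay at percentile 74.2 (ribosomal, mean 0.294, matched 0.265) and 25.8 (oxidative phosphorylation, mean 0.214, matched 0.253). The shallow libraries ntg TAC 5 and 6 are argued against as a cause, since without them the means were 1.09 and 0.818 times those with them. Without the near-identical libraries TG TAC 3 and 7 the ribosomal mean was 0.442 times as large, and it had camera adjusted p = 0.109; the oxidative phosphorylation mean was 0.735 times as large (adjusted p = 0.000779), so their part in it stays open. An effect of the transgene on which messages Ago2 binds was not tested apart from length.

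Other splits of the same hearts show whether chance can be excluded for a number of calls. It can be excluded for mRNA TG against ntg in TAC hearts (3584 genes; highest other split 797), TAC against sham in ntg (2505; 5) and in TG hearts (1857; 384), the same 3 in RISC (2050; 425, then 1470; 126, then 1151; 103) and RISC relative to mRNA in TAC hearts (136; 2), where the real split alone, 1 of 100, gave as many. In sham hearts the 10 splits are too few: mRNA 2627 (highest other 3), RISC 782 (2) and RISC relative to mRNA 35 (0; 1473 genes at unadjusted p below 0.05 in the real split by edgeR). For the difference of the transgene effect the splits decide nothing, although a share was set beforehand: 0 of the 99 others were free of the transgene effect itself, as each exchanges unequal shares of sham and TAC hearts. Of 100 splits 7 called at least 12 genes in mRNA (highest other 3992), 5 called at least 46 in RISC (1202) and 6 called at least 2 for RISC relative to mRNA (77). The highest point to that structure, as they exchange most TAC hearts.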

How the results depend on the processing

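The covariates, the left-out Rn45s and shallow libraries and the summed RISC libraries TG TAC 3 and 7 were chosen after the data were seen; all other alternatives were planned. Values are numbers of genes called unless said otherwise, and the cause was not tested for values that moved.

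With the adipocyte covariate the counts were 827 (mRNA TG against ntg, sham; 2627 without it), 768 (mRNA TAC against sham, ntg; 2505), 1 (mRNA interaction; 12) and 19 (RISC interaction; 46). In mRNA TG against ntg, sham, signs turned for Acsm3 (0.19), Tmem45b (0.29), Pck1 (1.39) and Cidec (1.08), and in mRNA TAC against sham, ntg, for Pck1 (0.89). Of the 2627 sham calls 782 were kept: folds stayed near their size (median ratio 0.972), 116 of them shrank to under 0.5 of it, and standard errors grew (median ratio 1.44). Of the 2505 TAC calls in ntg 710 were kept (median ratios 0.969 for folds and 1.41 for standard errors). With the length covariate RISC counts were 172 (TG against ntg, TAC; 2050), 295 (TAC against sham, ntg; 1470) and 9 (interaction; 46), and Rplp2 turned to -0.07 in TG against ntg, TAC. Of those 2050 calls 146 were kept, with median ratios of 0.771 for folds and 1.7 for standard errors.

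DESeq2 called 70 (mRNA interaction; 49 higher, 21 lower), 130 (RISC interaction), 122 (RISC relative to mRNA, sham; 61 higher, 61 lower), 329 (the same, TAC; 203 higher, 126 lower) and 26 (its interaction). Its calls shared 30 higher and 7 lower genes between sham and TAC for RISC relative to mRNA, against 15 and 2. Only the compared groups gave 1009 in mRNA TAC against sham, TG. No filter gave 1 in the interaction of RISC relative to mRNA, where leaving out the shallow libraries gave 0 and summing TG TAC 3 and 7 gave 0 (edgeR; 2 called and 1123 at unadjusted p below 0.05 with them; DESeq2 26).

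With the heart as a block, RISC relative to mRNA gave 68 (sham; 35 without it), 236 (TAC; 136) and 5 (interaction; 2), and camera called 6 lists in place of 1 in sham hearts. The replicate number as a block gave 1062 (mRNA TAC against sham, TG), 840 (RISC TAC against sham, ntg) and 685 (RISC TAC against sham, TG), although numbers were not taken to pair hearts across groups. With an estimated correlation camera called 1 list in mRNA TAC against sham, ntg (adult contraction) and 1 in RISC TG against ntg, TAC (histones), and 0 in the other 11 comparisons (1 to 15 with the preset correlation).

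Leaving out each replicate gave 1473 to 2689 (mRNA TAC against sham, ntg), 1020 to 1953 (mRNA TAC against sham, TG), 1 to 22 (mRNA interaction), 441 to 926 (RISC TG against ntg, sham), 730 to 1487 (RISC TAC against sham, ntg), 510 to 1381 (RISC TAC against sham, TG), 5 to 66 (RISC interaction), 8 to 43 (RISC relative to mRNA, sham) and 0 to 9 (its interaction; edgeR). It was 1772 to 2818 and 3174 to 3728 for mRNA TG against ntg in sham and TAC, 1579 to 2053 for RISC in TAC and 91 to 181 for RISC relative to mRNA in TAC hearts; without TG TAC 5 this last split into 89 higher and 18 lower. The largest shift of the median of all genes by an alternative was 0.0293 log2 units. Planned analyses of seed sites were not run, since no sequence was there.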

Other observations

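The tests of islet transcripts and of near-identical libraries, and the look at clock genes, were chosen after the data were seen.

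Hormone RNA of pancreatic islets was present in 8 TAC mRNA libraries, ntg TAC 2, 3, 4 and 5 and TG TAC 1, 2, 3 and 7. Ins1 stood at 24.5 ± 7.9 CPM and Ins2 at 58.2 ± 19.7 CPM in these, and at up to 0.401 and 0.751 CPM in the other 12. A source in pancreatic islet RNA may explain it: of 5 other islet hormone genes (Gcg, Ppy, Pyy, Sst, Iapp), 4 had counts over 3 in at least 7 of the 8 libraries and in 0 of the other 12. Gcg was at 1.18 CPM and Iapp at 0.843 CPM, and the exocrine gene Cpa1 was at 0.13 CPM. The 8 libraries hold 4 ntg and 4 TG hearts, so the transgene comparison could be made in each part: 1794 genes were called among libraries with islet RNA, 1716 of them also called over all 14, and 1092 among those without, 1068 of them also called over all 14. edgeR's test of a difference between these parts called 0 of 14014 genes (323 at unadjusted p below 0.05). Presence of islet RNA as a covariate gave 3646 calls, against 3584.

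RISC libraries TG TAC 3 and TG TAC 7 were the most alike of 96 pairs (chi-square per gene 2.11, next lowest 4.85, counting noise alone 1). RISC TG TAC 7 correlated with its own mRNA library (0.29), while RISC TG TAC 3 correlated with the mRNA of TG TAC 7 (0.25) and not with its own (-0.04). The same RNA in both tubes was not tested by any other measure, so both were kept.

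In ntg mRNA 5 circadian clock genes, picked by their values, were called between TAC and sham; no list of them was tested. Arntl was at -1.47 (SE 0.49, adjusted p = 0.0445, edgeR), Nfil3 at -1.44 (SE 0.19, adjusted p = 3.92e-05), Per3 at 0.84 (SE 0.13, adjusted p = 0.000167), Dbp at 1.53 (SE 0.41, adjusted p = 0.0158) and Bhlhe41 at 0.97 (SE 0.19, adjusted p = 0.00127). The hour of collection is not in the labels, and the cause was not tested.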
